A study of Mus musculus with 13 samples.

How the data were processed

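Total RNA of the proximal small intestine of 13 mice was hybridised to Illumina MouseRef-8 v2.0 BeadChips, a 1-colour array with 25697 probes in the deposited table. Per the labels, 8 mice were controls and 5 received ezetimibe at 0.005% of the chow, and each array is a separate biological replicate. The deposited table of unnormalized values holds, per the file headers, a mean bead signal (an intensity on a linear scale) and a detection p-value for each probe and array. Their medians differed between the slides. The software that exported them is not given in the sources used here. A table of processed values of the same arrays was also deposited. Per the series' design text, the authors normalized by quantiles, corrected for batch with Combat, kept probes with a fold change of at least 1.1 and tested with an intensity-based moderated statistic at a false discovery rate of 10%. The deposited processed values are intensities on a linear scale, and their column medians all lay between 236.09 and 236.297. The version of those programs, and whether these values were centred or given an offset, are not given in the sources used here. After slide means were taken out, each of those columns correlated best with its own array (r across probes 0.425 to 0.862, against at most 0.33 with another array), so their columns are in the stated order. Only 3 of their tested probes differed between slides, against 6330 in the unnormalized table after quantile normalization.

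Slide and position on the slide came from the array names in the table and were treated as technical batches. Both slides held both groups. For the main analysis, the signal was background-corrected with normexp from the detection p-values, given an offset of 16, quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 5 of 13 arrays were tested, whatever the group, which left 11887 probes (46.3%) for 8974 genes. A linear model with slide and group was fitted per probe with lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjusted p under 0.10 counted as past the threshold. A fixed slide term stood in for the batch correction. Slide-adjusted levels are the log2 intensities with the fitted slide difference taken out. Standard errors are those of the moderated fit. Different probes of a gene were tested apart, and for lists the brightest tested probe of a gene was used. Levels of different probes were compared only to find the brighter one.

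Gene names came from the symbols in the table, updated through a RefSeq gene table of the mouse assembly GRCm38.p6. Of the probes, 20439 had a current symbol, 4134 were renamed through a synonym of 1 gene, 1104 kept the file's name and 20 held a date in place of a symbol and stayed unnamed. No coordinates were used. Genes without a named probe were not analysed here.

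The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. There were 33 lists, 4 on sterols and 29 on other metabolic, immune, stress and cell type genes. Lists were tested with limma's camera with a preset correlation of 0.01 and adjusted over the 33 lists, and again with a correlation estimated from the data. The rotation test fry was run beside it. It asks whether a list's genes move one way and does not compare the list with other genes. Its adjusted p was 2.54e-06 for the cholesterol synthesis enzymes, 0.000583 for the other SREBP2 targets and 0.253 or more for all other lists. Named genes were the 10 largest rises and 10 largest falls past the threshold with 1 symbol (1 probe per gene, fewer where fewer passed), then a fixed set, of which Npc1l1, Abcg5, Abcg8, Abcb1a, Abcb1b, Abca1 and Scarb1 are given whether or not they passed and the others are not reported here, and per list up to 4 members past the threshold with the largest change or, where none passed, up to 2 with the smallest p. Other probes past the threshold are named as chosen after their values were seen. A pair of lists written later, of NRF2 targets and of stomach markers, were tested after the main results.

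The alternatives were no background correction, normexp with an offset of 50 without detection p-values, median scaling, the deposited processed values with and without a slide term, no filter, detection p under 0.01 on all arrays, no slide term, slide as a random block, each slide alone, position as a covariate, eBayes without a trend and with robust estimation, array weights, replicate number as a block, an adjusted p under 0.05, the fold prefilter, camera with an estimated correlation, the mean over all probes of a gene, and leaving out each array in turn. The level of exocrine pancreas markers as a covariate, leaving out the array highest in them in each group before slide adjustment (control 4 and ezetimibe 4), and further settings for the product of slide and treatment were added after seeing the data. The authors' moderated statistic and Combat were not run again.

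The procedure was tested on simulated data with the real arrays' layout and 200 of 11887 probes changed, 50 at each size, for ezetimibe against control. It recovered 62% of those changed by 0.5, 98% at 1, 98% at 1.5 and 100% at 2 (log2), with 9.6% of its calls among unchanged probes. A single list shifted by 0.5 was found and no other list was.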

Results

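Gene expression was measured in the proximal small intestine of 13 male C57BL/6J mice on Illumina MouseRef-8 v2.0 bead arrays, 1 array per mouse. Of these, 8 mice ate regular chow and 5 ate the same kind of chow with 0.005% ezetimibe. Ezetimibe is a cholesterol absorption inhibitor that binds NPC1L1, the sterol uptake protein of the enterocyte brush border. The arrays lay on 2 slides, with 4 control and 2 ezetimibe arrays on slide 1 and 4 control and 3 ezetimibe arrays on slide 2. The median probe signal ran from 146.9 to 152.8 on slide 1 and from 120.7 to 127.9 on slide 2, and between 11085 and 12380 of the 25697 probes were detected per array. Pearson's r between arrays, taken across probes, lay between 0.952 and 0.989. In all, 6330 probes differed between the slides at an adjusted p under 0.10 in limma, so slide was a term of every model below unless another setting is named. The number of arrays limits the precision of every value.

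The first comparison asked which intestinal transcripts differed between ezetimibe-fed and control mice. Transcripts of the cholesterol synthesis pathway rose with ezetimibe. Cyp51, a lanosterol demethylase, rose by 1.86 ± 0.12 (log2 fold change ± SE, 8 control and 5 ezetimibe arrays; limma, adjusted p = 6.70e-07), from a slide-adjusted level of 7.67 ± 0.21 in controls to 9.53 ± 0.23 with ezetimibe (log2 intensity, mean ± SD). Sqle, the squalene epoxidase, rose by 1.67 ± 0.17 on one probe and by 1.56 ± 0.10 on another (limma, adjusted p = 0.000123 and 6.70e-07). Msmo1, a methylsterol oxidase, rose by 1.35 ± 0.11 and Fdps, the farnesyl diphosphate synthase, by 1.27 ± 0.11 (limma, adjusted p = 1.09e-05 and 1.33e-05). Of the 15 tested members of the list of cholesterol synthesis enzymes, 9 rose and 0 fell over all probes tested. Adjusted over the list alone, 13 rose. All 15 had a log2 fold change above 0, and their median was 0.90 (limma's camera, adjusted p = 2.13e-39; adjusted p = 0.000341 with an estimated correlation). The median was 0.83 on slide 1 and 0.84 on slide 2. Over 33 other settings it ran from 0.23 to 0.95, and the list passed in all of them.

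The further members that rose were named after their values were seen. They were Mvd (0.95 ± 0.14), Lss (0.93 ± 0.16), Pmvk (0.92 ± 0.17), Nsdhl (0.90 ± 0.13) and Hsd17b7 (0.80 ± 0.11), with adjusted p in limma between 0.00198 and 0.0433. Pmvk lost its call when control 8 or any single ezetimibe array was left out, with adjusted p between 0.11 and 0.136. The probes of Nsdhl differed, at 0.90, 0.83, 0.58 and 0.14. Hmgcs1, Mvk and Fdft1 were not analysed here, and Idi1 did not reach the detection filter.

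**Figure D1:**
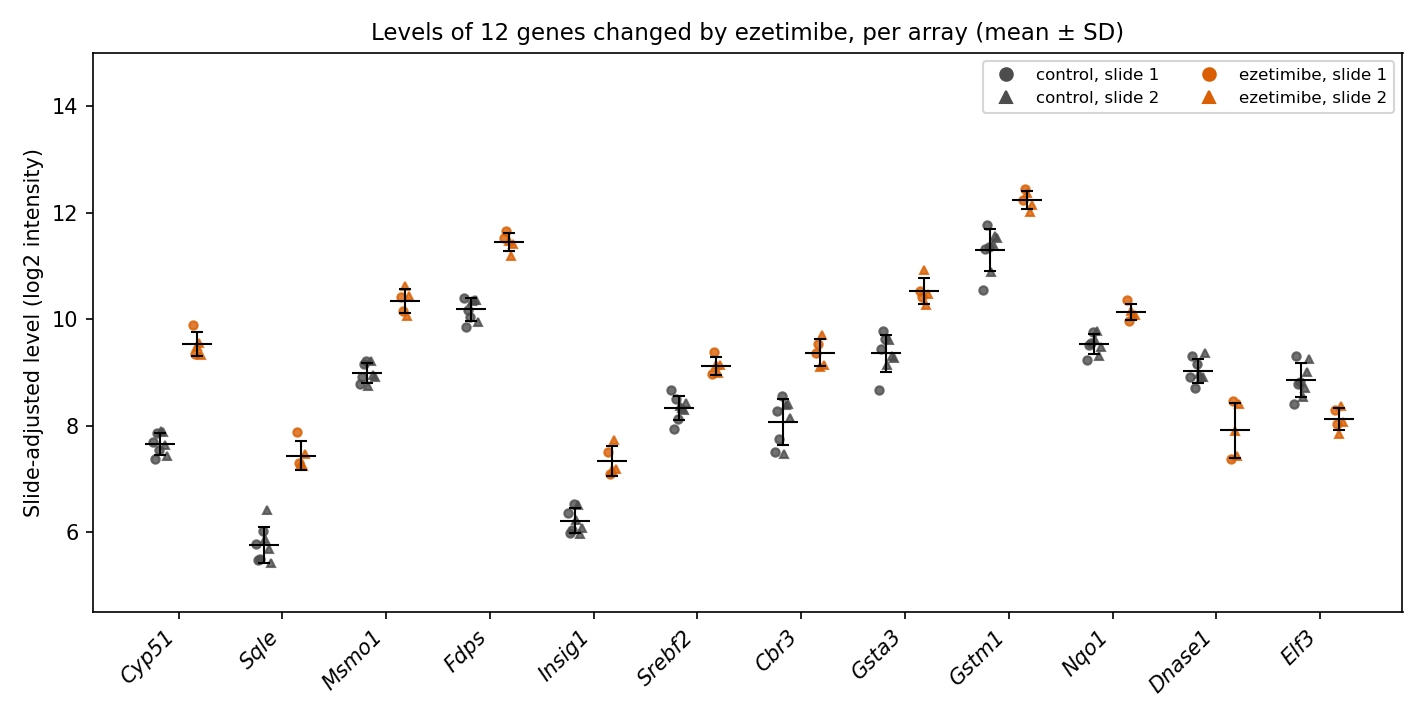
Slide-adjusted levels (log2 intensity, vertical axis) of genes that changed with ezetimibe, 1 point per array, with controls in grey and ezetimibe in orange, slide 1 as circles and slide 2 as triangles, and black marks for the mean ± SD. Cyp51, at 7.67 in controls and 9.53 with ezetimibe, shows the widest gap, and Dnase1 and Elf3 lie lower with ezetimibe.

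In the list of other targets of SREBP2, the transcription factor that activates genes of sterol synthesis and uptake, 3 of 9 tested members rose, 0 fell and 6 did not pass. Adjusted over the list alone, 6 rose. Insig1, whose protein holds SREBP precursors in the endoplasmic reticulum, rose by 1.12 ± 0.15 and 0.99 ± 0.17 on a pair of probes (limma, adjusted p = 0.00143 and 0.0142), while its other probe gave 0.09 ± 0.21 (adjusted p = 0.974). Srebf2, which encodes SREBP2, rose by 0.79 ± 0.12 and Aacs, an acetoacetyl-CoA synthetase, by 0.60 ± 0.11 (limma, adjusted p = 0.00361 and 0.0274). Without ezetimibe 1, 2 or 5 the adjusted p of Aacs lay between 0.112 and 0.158. Its call was also lost without the slide term, with the position as a covariate, on each slide alone and with the replicate number as a block. The same held without the arrays highest in pancreas markers. The Insig1 probe at 0.99 lost its call with the position as a covariate and on each slide alone. Srebf2 lost its call without the slide term, on slide 1 alone and with the replicate number as a block. The median of the list was 0.36 (camera, adjusted p = 5.20e-10; adjusted p = 0.00312 with an estimated correlation), with 0.40 on slide 1 and 0.33 on slide 2.

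Sterol transporters did not pass the test over all probes. Npc1l1 gave a log2 fold change of 0.087 ± 0.11 (limma, adjusted p = 0.938). Abcg5 and Abcg8, the subunits of the apical sterol exporter, gave -0.32 ± 0.08 and -0.34 ± 0.13 (limma, adjusted p = 0.199 and 0.734). Scarb1, a lipoprotein receptor, gave 0.30 ± 0.13 (limma, adjusted p = 0.772). The probes of Abca1 and Abcb1a were detected on 0 of 13 arrays and that of Abcb1b on 1, so these were not tested. In the list of LXR targets, genes activated by oxysterols, 0 of 7 tested members passed over all probes. Adjusted over the list alone, 1 rose and 2 fell, the latter being Abcg5 and Abcg8. The median was -0.085 (camera, adjusted p = 0.338). In the list of sterol and lipid uptake and chylomicron assembly, 0 of 17 tested members passed, Acsl5 gave 0.10 ± 0.06 (limma, adjusted p = 0.838), and the median was 0.051 (camera, adjusted p = 0.389). The direction of that list in the camera test, which need not be the sign of its median, turned on slide 1 alone (median -0.0087) and with the position as a covariate (median 0.011, adjusted p = 0.853), and the list passed with median scaling (median 0.14, adjusted p = 0.0381).

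**Figure D2:**
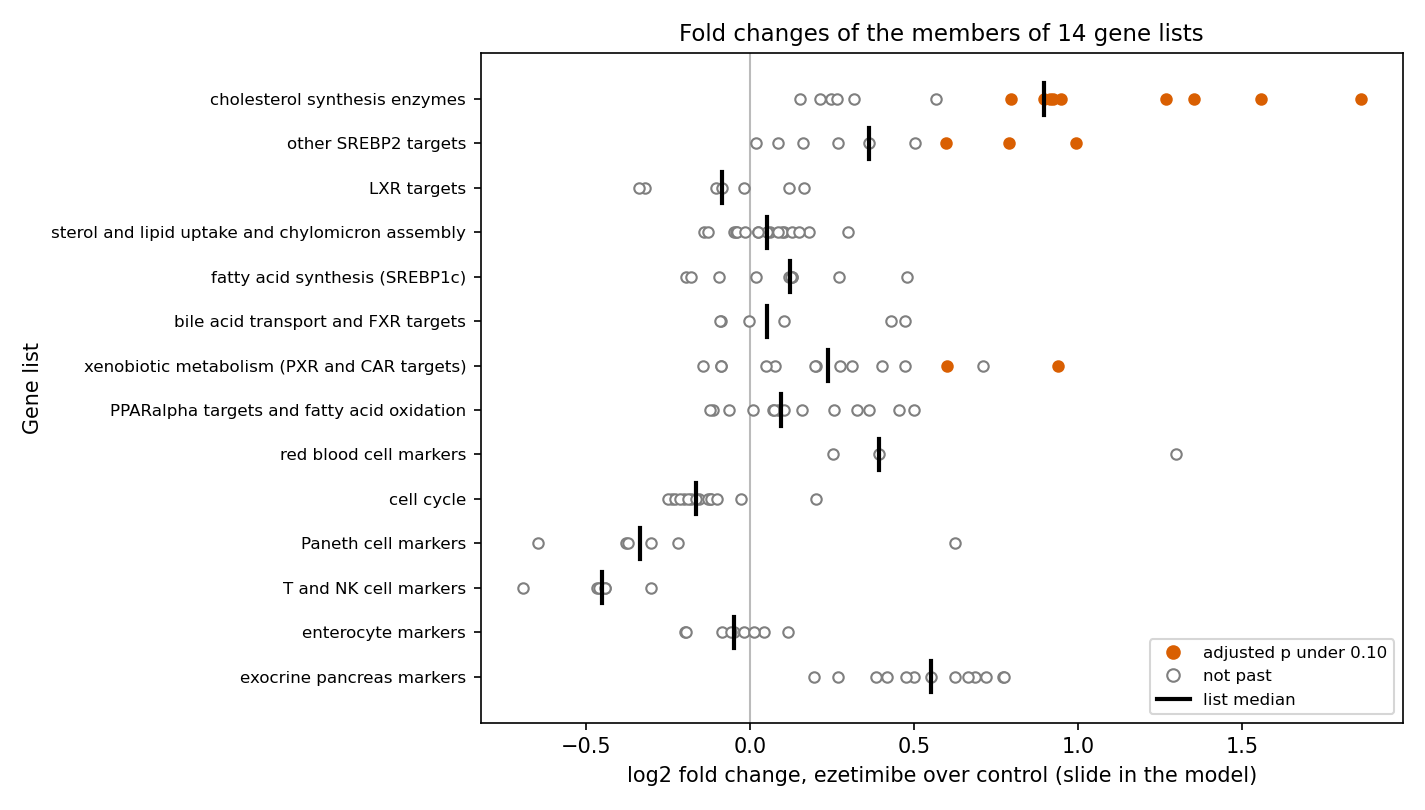
Log2 fold change of each tested member (horizontal axis) in gene lists fixed before the data were examined (vertical axis), 1 point per gene, orange where the adjusted p was under 0.10 and open where it was not, with a black line at the list median. All 15 cholesterol synthesis enzymes lie above 0, and the median of the LXR targets lies at -0.085.

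Over all 11887 tested probes, 30 changed, 28 up and 2 down, for 25 genes that rose and 2 that fell (limma, adjusted p under 0.10). At an unadjusted p under 0.05 there were 735. In 25 of those 27 genes, all 5 ezetimibe arrays lay beyond every control array of their own slide, and for Gss and Gclm 4 did. Within slides, 6 probes changed on slide 1 and 10 on slide 2, and without the slide term 17 changed. With only probes of at least 1.1-fold change entering the adjustment, as the series text describes, 81 changed, with all 30 among them. That filter picks probes by the effect that is then tested, so the adjusted p of this setting does not hold the false discovery rate.

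Outside the sterol lists, Cbr3, a carbonyl reductase, rose by 1.31 ± 0.19 and 1.26 ± 0.15 on its probes (limma, adjusted p = 0.00361 and 0.000643). Gsta3, a glutathione S-transferase, rose by 1.16 ± 0.16 on one probe (limma, adjusted p = 0.00217) and gave 0.19 ± 0.17 on another (adjusted p = 0.909). In the list of xenobiotic metabolism, fixed as targets of the receptors PXR and CAR, 2 of 14 tested members rose, 0 fell and 12 did not pass. Adjusted over the list alone, 7 rose. Gstm1 rose by 0.94 ± 0.17 on its brighter probe (limma, adjusted p = 0.0235), while its other probe gave -0.42 ± 0.17 (adjusted p = 0.745). The call of the brighter probe was lost without ezetimibe 2 (0.87, adjusted p = 0.154). It was also lost without the slide term, with the position on the slide as a covariate and on each slide alone. Nqo1, a quinone reductase, rose by 0.60 ± 0.10 (limma, adjusted p = 0.0142). The median of the list was 0.24 (camera, adjusted p = 2.54e-06; adjusted p = 0.468 with an estimated correlation), with 0.35 on slide 1 and 0.20 on slide 2. With the position on the slide as a covariate it was 0.064 (camera, adjusted p = 0.409). Aldh1a7, an aldehyde dehydrogenase (0.75 ± 0.16), Gss (0.44 ± 0.09) and Gclm (0.42 ± 0.09), both of glutathione synthesis, also rose and were named after their values were seen (limma, adjusted p = 0.0899, 0.0886 and 0.0772). Leaving out 1 array ended the call of Aldh1a7 in 9 of 13 cases (all but control 1, 3, 4 and 7; adjusted p up to 0.329). It ended that of Gss in 10 (all but control 3 and 6 and ezetimibe 1; up to 0.32) and that of Gclm in 9 (all but control 2, 4 and 6 and ezetimibe 1; up to 0.263).

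Further genes rose outside every list. Aldoc, an aldolase, rose by 1.08 ± 0.11 and the locus named LOC100040592 in the files by 0.99 ± 0.11 (limma, adjusted p = 5.57e-05 and 0.000326). Bglap3, of the osteocalcin family, rose by 1.12 ± 0.15 (limma, adjusted p = 0.0021) and was detected on 4 of 8 control and 5 of 5 ezetimibe arrays. Its size differed with the processing, down to 0.15 in the deposited processed values, where the call held. The call was lost on each slide alone (0.96 and 1.25, adjusted p = 0.531 and 0.168) and with the replicate number as a block. Mmab, of cobalamin metabolism (0.59 ± 0.12), Slc25a1, the mitochondrial citrate carrier (0.40 ± 0.07), and Rtkn (0.44 ± 0.09) were named after their values were seen (limma, adjusted p = 0.0625, 0.0244 and 0.0772). Mmab lost its call without control 8 or any ezetimibe array (adjusted p 0.103 to 0.313), Slc25a1 without ezetimibe 2, 3 or 5 (0.107 to 0.148), and Rtkn in 10 of 13 cases (all but control 3, 6 and 7; 0.11 to 0.245). The other probe of Rtkn gave -0.058 ± 0.12. The 2 genes that fell were Dnase1, a secreted DNA-degrading enzyme (-1.12 ± 0.18), and Elf3, an epithelial transcription factor (-0.73 ± 0.15; limma, adjusted p = 0.0129 and 0.0843). Dnase1 lost its call without the slide term, on each slide alone and with the replicate number as a block. Over all settings its log2 fold change ran from -1.31 to -0.59. The other probes of Elf3 gave -0.11 ± 0.11 and -0.067 ± 0.14, and its call was lost without control 2, 4, 7 or 8 or ezetimibe 1, 2, 3 or 5 (log2 fold change -0.79 to -0.66, adjusted p 0.107 to 0.313).

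The next comparison covered other metabolic, immune and cell type lists, 29 in all, of which 6 passed with the preset correlation of camera and 0 with an estimated one. The estimated correlation of these 6 lists ran from 0.167 (PPARalpha targets and fatty acid oxidation) to 0.927 (T and NK cells), against the preset 0.01. Their p-values with the preset one, within slides and in other settings too, are therefore too small to rely on. Red blood cell markers were higher with ezetimibe, with a median of 0.39 over 3 tested members (camera, adjusted p = 0.00387; adjusted p = 0.361 with an estimated correlation), 0.64 on slide 1 and 0.20 on slide 2, where the call was lost (camera, adjusted p = 1.09e-06 and 0.316). With the position as a covariate the median was 0.52 (adjusted p = 0.00266). Hba-a1, an alpha globin, gave 1.30 ± 0.30 and Alas2, of haem synthesis, 0.39 ± 0.19 (limma, adjusted p = 0.146 and 0.807). The list median was the value of Alas2 itself, over all arrays and on each slide alone. The Alas2 probe was dim, at 5.00 in controls (slide-adjusted log2 intensity). It was detected on 5 control arrays, not all of them, and on all 5 ezetimibe arrays, so this median was measured near the floor. Hba-a1 passed in some other settings, with a lowest adjusted p of 0.0165 under median scaling. Targets of PPARalpha and fatty acid oxidation had a median of 0.095 (camera, adjusted p = 0.0148; adjusted p = 0.623 with an estimated correlation), with 0 of 14 members past over all probes and 2 that rose adjusted over the list alone. Acadvl gave 0.26 ± 0.06 and Ehhadh 0.36 ± 0.10 (limma, adjusted p = 0.173 and 0.338). The median was 0.11 on slide 1, where the call was lost, and 0.26 on slide 2 (adjusted p = 0.198 and 0.00219). The call was also lost without ezetimibe 5 (median 0.068, adjusted p = 0.105), without the slide term (0.11, adjusted p = 0.256) and with the position as a covariate (0.12, adjusted p = 0.409).

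Markers of T and NK cells were lower with ezetimibe, with all 6 tested members below 0 and a median of -0.45 (camera, adjusted p = 0.00407; adjusted p = 0.623 with an estimated correlation). Cd3e gave -0.47 ± 0.25 and Ccl5 -0.69 ± 0.38 (limma, adjusted p = 0.834 and 0.838). The median was -0.48 on slide 1 and -0.44 on slide 2, and the call was lost without ezetimibe 1 (median -0.32, adjusted p = 0.119). With the position as a covariate the median was -0.78 (camera with the preset correlation, adjusted p = 9.79e-06). The estimated correlation of these genes was 0.927, so that p-value is too small to rely on. Paneth cell markers had a median of -0.34 over 6 members (camera, adjusted p = 0.0179; adjusted p = 0.623 with an estimated correlation), -0.43 on slide 1 and -0.13 on slide 2 (adjusted p = 0.000555 and 0.286). They lost the call on slide 2 alone, without ezetimibe 5 (median -0.27, adjusted p = 0.118) and with the position as a covariate (-0.071, adjusted p = 0.68). Lyz1, a lysozyme, gave -0.30 ± 0.13 and Pla2g2a, a secreted phospholipase, -0.38 ± 0.18 (limma, adjusted p = 0.745 and 0.806). Cell cycle genes had a median of -0.16, with 14 of 15 members below 0 (camera, adjusted p = 0.0154; adjusted p = 0.773 with an estimated correlation), -0.01 on slide 1 and -0.27 on slide 2. Their call was lost on slide 1 alone (adjusted p = 0.75), without control 7, ezetimibe 2 or ezetimibe 4 (medians -0.12 to -0.085, adjusted p 0.126 to 0.406) and with the position as a covariate (-0.074, adjusted p = 0.432). Mcm7 gave -0.24 ± 0.16 and Mcm6 -0.18 ± 0.12 (limma, adjusted p = 0.861 and 0.863).

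Exocrine pancreas markers ranged widely between arrays of both groups. The mean slide-adjusted level of the 13 markers ran from 5.98 in control 7 to 13.19 in ezetimibe 4 (log2 intensity), and was 9.09 ± 2.06 in controls (SD, n = 8) and 9.63 ± 3.10 with ezetimibe (SD, n = 5). Prss2, a trypsin, gave 0.69 ± 0.71 and Cel, a bile salt-dependent lipase, 0.77 ± 1.33 (limma, adjusted p = 0.921 and 0.96). The difference of 0.54 between the groups was within the spread between arrays (exact permutation test within slides, 525 splits, two-sided p = 0.716; camera, adjusted p = 0.389). With the pancreas level as a covariate, 31 probes changed, 26 of them among the 30. Without control 4 and ezetimibe 4, the arrays highest in these markers in each group before slide adjustment, 27 changed, 24 of them among the 30. Both settings were chosen after seeing the data.

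**Figure D3:**
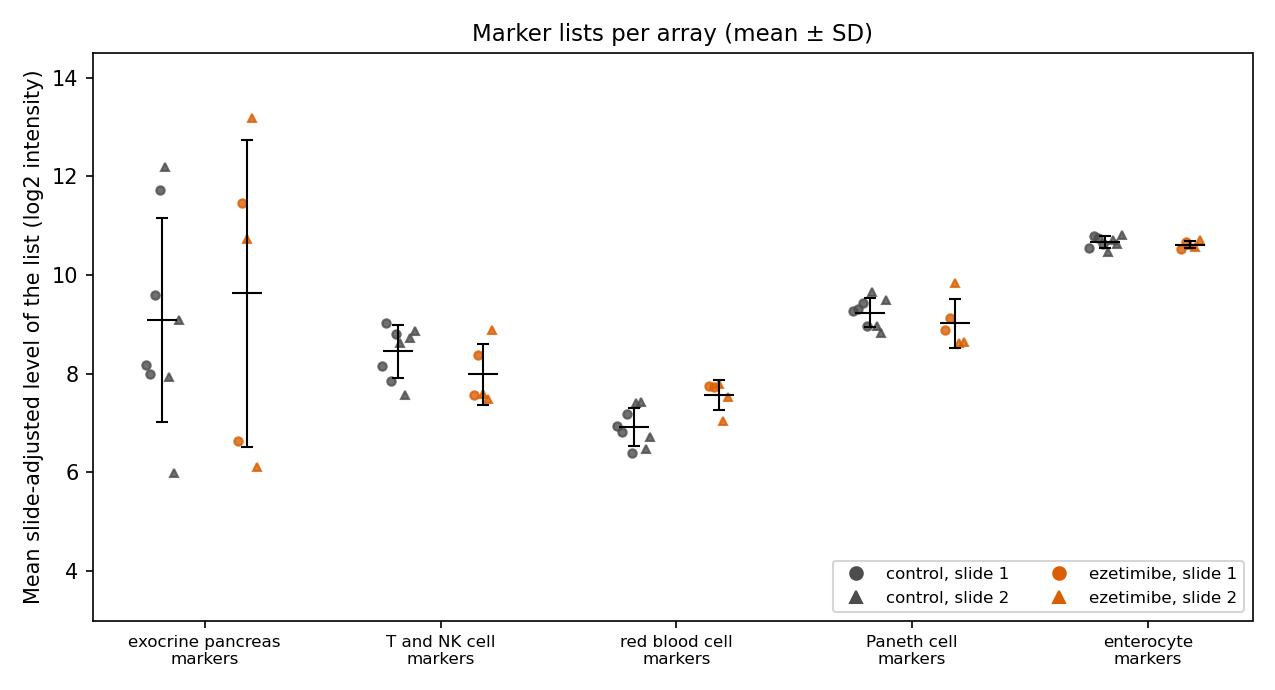
Mean slide-adjusted level of marker lists (log2 intensity, vertical axis), 1 point per array, with controls in grey and ezetimibe in orange, slide 1 as circles and slide 2 as triangles, and black marks for the mean ± SD. Exocrine pancreas markers span 5.98 to 13.19 across the arrays, while enterocyte markers stay close together in both groups.

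The other 22 lists of that comparison did not pass, and 0 of their members passed over all probes. Fatty acid synthesis had a median of 0.12 (camera, adjusted p = 0.104), with Acss2 at 0.27 ± 0.08 and Me1 at 0.48 ± 0.17, and 2 members rose adjusted over the list alone. It passed in 14 of 33 other settings. Bile acid transport and FXR targets had a median of 0.051 (camera, adjusted p = 0.173), with the exporters Abcc2 at 0.47 ± 0.11 and Abcc3 at 0.43 ± 0.16, and 2 rose adjusted over the list alone. It passed in 7 of 33 other settings. Duodenal markers had a median of 0.13 (camera, adjusted p = 0.338), with Pdx1 at 0.18 ± 0.09 and Cybrd1 at 0.58 ± 0.31, and ileal markers of -0.047 (adjusted p = 0.859), with Gcg at -0.23 ± 0.21 and Pyy at 0.29 ± 0.27. Circadian clock genes had a median of 0.062 (adjusted p = 0.338), with Bhlhe40 at 0.31 ± 0.15 and Nr1d1 at 0.49 ± 0.27. Immediate early genes had a median of 0.026 (adjusted p = 0.551), with Junb at 0.19 ± 0.12 and Klf4 at 0.23 ± 0.15. Subunits of the respiratory chain had a median of -0.0084 (adjusted p = 0.499), with Ndufb3 at -0.15 ± 0.06 and Ndufa1 at -0.12 ± 0.09. The unfolded protein response had a median of -0.017 (adjusted p = 0.859), with Calr at -0.31 ± 0.14 and Herpud1 at -0.19 ± 0.11.

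Among epithelial lists, enterocyte markers had a median of -0.049 (camera, adjusted p = 0.462), with Treh at -0.20 ± 0.08 and Mep1a at -0.19 ± 0.13. Goblet cell markers had a median of -0.012 (adjusted p = 0.859), with Tff3 at -0.13 ± 0.10 and Spdef at 0.098 ± 0.12. Enteroendocrine markers had a median of -0.02 (adjusted p = 0.449), with Sst at -0.39 ± 0.20 and Gip at -0.24 ± 0.13. Tuft cell markers had a median of -0.046 (adjusted p = 0.931), with Trpm5 at 0.23 ± 0.32 and Dclk1 at -0.13 ± 0.19. Crypt stem cell markers had a median of -0.21 (adjusted p = 0.338), with Cdca7 at -0.26 ± 0.13 and Olfm4 at -0.25 ± 0.23.

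Among stromal and immune lists, smooth muscle markers had a median of -0.0016 (camera, adjusted p = 0.859), with Cnn1 at -0.11 ± 0.13 and Synm at -0.11 ± 0.16. Fibroblast markers had a median of 0.014 (adjusted p = 0.95), with Col6a1 at -0.22 ± 0.12 and Dcn at 0.28 ± 0.16. Endothelial markers had a median of -0.045 (adjusted p = 0.552), with Tie1 at -0.17 ± 0.14 and Vwf at -0.16 ± 0.16. Adipocyte markers had a median of -0.044 (adjusted p = 0.859), with Lep at 0.16 ± 0.12 and Cfd at -0.54 ± 0.50. Enteric neuron markers had a median of -0.16 (adjusted p = 0.81), with Vip at 0.49 ± 0.14 and Uchl1 at -0.22 ± 0.23, and 1 rose adjusted over the list alone. B and plasma cell markers had a median of 0.12 (adjusted p = 0.449), with Tnfrsf17 at 0.50 ± 0.18 and Cd79b at -0.14 ± 0.17, and 1 rose adjusted over the list alone. Macrophage and dendritic cell markers had a median of 0.067 (adjusted p = 0.879), with Cd68 at -0.33 ± 0.15 and Cd14 at 0.19 ± 0.16. The interferon response had a median of -0.043 (adjusted p = 0.551), with Gbp2 at -0.23 ± 0.22 and Zbp1 at -0.082 ± 0.14. MHC class II had a median of -0.038 (adjusted p = 0.931), with H2-Aa at 0.22 ± 0.36 and Ciita at 0.14 ± 0.29. On slide 1 alone the MHC class II median was 0.59 and on slide 2 it was -0.45 (camera with the preset correlation, adjusted p = 1.65e-05 and 0.00219). The estimated correlation of these genes was 0.956, far above the preset 0.01, so these p-values are too small to rely on. H2-Aa and Ciita passed in no setting. The difference between slides was not tested for the list. The test and the median differed in sign for fibroblast and enteric neuron markers, and the median and the mean for MHC class II (mean 0.0031), the unfolded protein response (0.015), tuft cell (0.019) and enteric neuron markers (0.036).

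The last comparison asked whether the effect of ezetimibe differed between the slides. In limma, 0 of 11887 probes passed for the product of slide and treatment, and 317 had an unadjusted p under 0.05, fewer than chance gives on average. The slides held 2 and 3 ezetimibe arrays, so the lack of calls does not show that the effects were equal. Cyp51 rose by 2.01 on slide 1 and 1.75 on slide 2, Cbr3 by 1.43 and 1.22 on its leading probe, and Dnase1 gave -1.10 and -1.13.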

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

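The levels looked up in the highest split, and its fit with the pancreas covariate, were chosen after that split was seen. The samples were screened for arrays far from the rest of their group, in 250 sets of 5 or 8 values for the named probes and the list means. In 7 sets the highest or lowest array was farther from its nearest neighbour than Dixon's test allows, where chance gives about 1 in 20, or 12.5 sets. All values are slide-adjusted log2 intensities. For Scarb1, control 4 lay at 6.39 and the nearest control at 6.07. For Dclk1, ezetimibe 4 lay at 5.72 and the nearest ezetimibe array at 5.99. For Synm, control 6 lay at 7.82 and the nearest control at 7.35. For Alas2, ezetimibe 4 lay at 4.84 and the nearest ezetimibe array at 5.44. For Slc25a1, control 5 lay at 10.56, below the other controls, whose nearest was at 10.69. The mean of the xenobiotic metabolism list was 10.52 in ezetimibe 3 and 10.88 in the nearest ezetimibe array, and the mean of the respiratory chain list was 11.36 in control 1 and 11.44 in the nearest control.

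Among 100 splits of the 13 arrays into 8 and 5, the real one included, 4 gave at least the 30 probes of the real split. Among 100 splits that kept the real numbers per slide, 2 did. Both counts lay under the planned limit, but other splits gave more probes than the real one, so chance is not excluded. The highest other splits gave 132 and 36 probes, and further splits of the first kind gave 131 and 53. Splits with several times the real count point to another structure of the samples. The group of 5 in the split with 132 probes held control 1, 3 and 5 and ezetimibe 1 and 4. Its mean level was 1.14 higher (log2) than in the other arrays for pancreas markers and 1.11 higher for interferon response genes. It was 0.55 lower for T and NK cell markers and 0.41 lower for MHC class II. With the pancreas level as a covariate this split still gave 134 probes.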

How the results depend on the processing

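The pancreas covariate, the setting without the pancreas-high arrays and the other settings for the product of slide and treatment were chosen after seeing the data. There were 35 settings besides the main one, 31 of them for genes and 33 for lists. All 30 called probes kept their sign in every setting that gave them a value, and 6 kept their call in all, namely those of Cyp51, Sqle (both), Msmo1, Fdps and Aldoc. Of 62 named probes not called, 44 kept their sign and 5 passed in some setting: Hba-a1 in 8 of 31, Acadvl with the position covariate, Abcg5 without control 6, and Nr1d1 and Lyz1 in the setting of the next paragraph. Against 30 probes, 17 changed without a slide term, 6 on slide 1 alone, 10 on slide 2 alone and 81 with the fold prefilter. The single-slide fits hold fewer arrays. The prefilter adjusts over fewer probes, which it picks by the effect then tested, so its count cannot be set beside the others. For the slide term the cause was not tested. Leaving out each array in turn gave 20 to 44. Of the main calls, 93.3% were higher with ezetimibe, and 83.3% with the position covariate. Median scaling moved the median of all probes to 0.088 from -0.001. The product of slide and treatment gave 0 probes also with no filter and with no background correction. The cholesterol synthesis and other SREBP2 target lists passed in all 33 settings, with medians of 0.23 to 0.95 and 0.12 to 0.50. The uptake list passed with median scaling (0.14, adjusted p = 0.0381) and the LXR list with the mean over all probes of a gene (-0.10, adjusted p = 0.0751). Some lists that did not pass did so in other settings: fatty acid synthesis in 14 of 33, among them the deposited processed values, the position covariate, array weights and the pancreas covariate, and bile acid transport and FXR targets in 7. MHC class II and pancreas markers did in 5 each and enteroendocrine markers in 4. Interferon, clock, immediate early, enterocyte, crypt stem cell, fibroblast and duodenal lists did in 1 each. The other lists past the threshold numbered 6, and 10 without the pancreas-high arrays, 0 with an estimated correlation, and 6 to 8 with 1 array left out. The cause was not tested for these. The signal over background limits dim probes, so Bglap3, detected on 4 of 8 control arrays, was measured near the floor. Mcm7, Mep1a, Tie1, Cnn1, Lep and Alas2, among others, were also not detected on every array.

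The replicate numbers do not pair the animals. Same-numbered arrays correlated in their deviations at 0.12, -0.13, 0.047, 0.36 and -0.42 after slide adjustment, for numbers 1 to 5. With the replicate number as a block, 23 probes changed, 15 of them among the 30, with 78.3% higher, and 13 other lists passed. Under the block the uptake list passed (0.079, adjusted p = 0.0253), as did Nr1d1 and Lyz1. The test turned direction under the block for MHC class II (median 0.11), enterocyte (0.13), goblet (0.048), tuft (0.19), B and plasma cell (-0.38), macrophage (-0.15), pancreas (-1.57) and enteric neuron markers (-0.13). Among genes Zbp1 (0.011), Dclk1 (0.29), Cnn1 (0.052), Synm (0.058) and Cel (-1.34) turned.

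The direction of a list is that of its camera test, which need not be the sign of its median. In the cases that follow a direction turned, and the cause was not tested. With median scaling it turned for the unfolded protein response (median 0.11), respiratory chain (0.11), goblet (0.11), smooth muscle (0.13), fibroblast (0.066), macrophage (0.18) and enteric neuron lists (-0.078), and for Ndufa1 (0.042) and Tff3 (0.037). With the deposited processed values it turned for MHC class II, at -0.016 without and -0.023 with a slide term. With no filter it turned for tuft (0.045), fibroblast (0.075) and ileal markers (-0.033). Without the slide term it turned for MHC class II (-0.0045), tuft (-0.0026), smooth muscle (0.064) and fibroblast markers (0.052), and with slide as a random block for fibroblast markers (0.020). On slide 1 alone it turned for lipid uptake (-0.0087), interferon (-0.014), MHC class II (0.59), unfolded protein response (-0.0041), respiratory chain (0.0012), goblet (0.026), endothelial (0.12) and pancreas lists (-0.21). There Npc1l1 (-0.018), Gbp2 (0.095), Bhlhe40 (-0.046), Trpm5 (-0.20), Cel (-0.20) and Pyy (-0.084) turned too. On slide 2 alone it turned for smooth muscle (0.038), macrophage (-0.042) and enteric neuron lists (-0.21), and for H2-Aa (-0.38), Ciita (-0.45) and Gcg (0.024). With the position covariate it turned for lipid uptake (0.011), immediate early (-0.046), enteroendocrine (0.11), tuft (0.084), crypt stem cell (-0.0033), smooth muscle (0.036), fibroblast (0.11) and adipocyte lists (0.082), and for Olfm4 (0.015), Cfd (0.025) and Uchl1 (0.0099). With array weights it turned for MHC class II (0.13), goblet (0.0069), smooth muscle (0.048) and fibroblast lists (0.044). With the pancreas covariate it turned for MHC class II (-0.017). Without the pancreas-high arrays it turned for MHC class II (0.26), goblet (0.071), tuft (-0.018), smooth muscle (0.031) and pancreas lists (0.025). With the mean over all probes of a gene it turned for the unfolded protein response (0.017) and macrophage list (0.053).

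With 1 array left out in turn, the direction turned at least once for 12 lists and 7 genes. Their medians ran from -0.22 to 0.16 for interferon, -0.34 to 0.24 for MHC class II, -0.055 to 0.025 for the unfolded protein response, -0.12 to 0.048 for goblet, -0.14 to 0.13 for tuft, -0.082 to 0.078 for smooth muscle, -0.031 to 0.062 for fibroblast and -0.021 to 0.14 for macrophage lists. They ran from -0.34 to 1.53 for pancreas, -0.090 to 0.042 for adipocyte, -0.25 to -0.081 for enteric neuron and -0.092 to 0.0025 for ileal markers. The genes ran from -0.16 to 0.54 for H2-Aa, -0.17 to 0.36 for Ciita, -0.048 to 0.42 for Trpm5, -0.51 to 0.051 for Olfm4, -0.26 to 0.0083 for Synm, -0.25 to 1.83 for Cel and -0.82 to 0.0086 for Cfd.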

Other observations

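The tests of the pancreas markers and of the T and NK cell markers were chosen after those results were seen, as were the settings with a pancreas covariate and the NRF2 list without genes of other lists. The other tests of the detoxification genes were chosen before their results were seen, on a pattern noticed in these data. No list of genes that the transcription factor NRF2 is known to activate was fixed at the start, though some of these genes stood in other lists. A list of 27 such genes was therefore tested after the main results, of which 2 (Me1 and Abcc3) stand in other lists as well. Of its 21 tested members 19 lay above 0, with a median log2 fold change of 0.24, and 0 passed over all probes. Adjusted over the list alone, 10 rose. Without Me1 and Abcc3, the median of the 19 others tested was 0.23 (camera, p = 0.00173 with an estimated correlation). Srxn1, a sulfiredoxin, gave 0.37 ± 0.11, Gsta4 0.36 ± 0.12, Pgd, of the pentose phosphate pathway, 0.28 ± 0.08, and Esd, an esterase, 0.43 ± 0.14 (limma, adjusted p = 0.439, 0.471, 0.32 and 0.563). Hmox1, another known target, gave -0.34 ± 0.22 and Txnrd1 0.077 ± 0.12 (limma, adjusted p = 0.861 and 0.955).

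A rise of NRF2 target genes may account for the higher detoxification transcripts (Cbr3, Gsta3, Nqo1, Gstm1, Gclm, Gss and Aldh1a7, picked from the called genes after their values were seen, median 0.75). Nqo1 and Gstm1 also stand in the fixed xenobiotic list of PXR and CAR targets, and these regulators were not compared with NRF2. The list of 27 shifted upward with an estimated correlation (camera, p = 0.000807), and its p lay between 0.000195 and 0.0555 over 29 other settings, the highest of them on slide 2 alone. With the pancreas level as a covariate the median of the 7 genes was 0.75 ± 0.12 (SE of their mean), and 5 of the 7 kept their calls. These genes were picked in a fit over the same arrays, so that median does not decide whether pancreas RNA explains their rise. The list of 27 was not picked by its values. Its median was 0.23 with that covariate against 0.24 without it, so the pancreas level did not account for the shift of that list. An effect of one slide alone stays open for the 7 genes. Their medians of 0.73 and 0.76 within the slides come from genes picked in a fit over both. The fixed xenobiotic list had medians of 0.35 and 0.20 within the slides (camera with the preset correlation, adjusted p = 5.95e-07 and 0.00219). Its estimated correlation over all arrays was 0.426, far above the preset one, and with it camera gave adjusted p = 0.468. The p-values within the slides are therefore too small to rely on and do not settle the question. The position on the slide stays open: as a covariate it left a median of 0.61 ± 0.13, with 3 of the 7 past the threshold, and on slide 1 both ezetimibe arrays lay after all controls.

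Pieces of pancreas in some gut samples are a candidate explanation for the wide range of pancreas transcripts. Each of the 13 markers correlated with the mean of the others at r = 0.899 or more across the slide-adjusted arrays, and none of them stands in another list. Cela2a, an elastase, ran from 7.00 to 15.32, Pnlip, the pancreatic lipase, from 5.45 to 14.04 and Try4, a trypsin, from 5.29 to 14.02 (log2 intensity). On all arrays 6 of the 13 markers were detected, so gut may express some of them. No biological explanation was tested, and the labels name no step that would remove such tissue.

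None of the 10 T and NK cell markers stands in another list. Lower T and NK cell markers with ezetimibe may come from a swing of a few arrays in genes that move together. Their estimated correlation was 0.927, and with it camera gave p = 0.17. Markers of the same cell type would move together in either case, so this test cannot tell such a swing from an effect of ezetimibe. Dilution by pancreas RNA would lower every gut cell type alike. The mean shift of T and NK cell markers was -0.47 ± 0.34 (SE). It was -0.047 ± 0.063 for enterocyte and -0.013 ± 0.088 for goblet cell markers. Smooth muscle (-0.013 ± 0.13), fibroblast (0.030 ± 0.11) and macrophage markers (0.023 ± 0.11) did not fall by that much either. These values argue against dilution as the whole of a shift of -0.47. The T and NK shift minus the enterocyte shift was -0.42 ± 0.33, so a smaller fall shared by all of them stays open. With the pancreas level as a covariate the T and NK median was -0.44, against -0.45 without it. An effect of ezetimibe on these cells was not tested apart from these and stays open.

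Stomach markers were also looked for after the main results, and 2 of 9 were tested. Gkn3, a gastrokine, was at 9.85 ± 2.18 in controls and 10.58 ± 2.33 with ezetimibe (slide-adjusted log2 intensity, mean ± SD), and Pgc, a pepsinogen, at 7.01 ± 0.96 and 7.16 ± 1.01. The pair had a median log2 fold change of 0.45 (camera, p = 0.547; p = 0.676 with an estimated correlation).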
